A study of Homo sapiens with 18 samples.

How the data were processed

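Total RNA from human prostate cancer cell lines was measured on 18 Illumina HumanHT-12 type bead arrays, 3 in each of 6 groups. Per the labels, RNA was extracted with a Zymo kit, checked on an Agilent Bioanalyser, and made into biotin-labelled cRNA with the Ambion MessageAmp kit. The labels placed every array in a group: 22Rv1 or LNCaP cells with the tetO-Gal4 construct, without or with doxycycline (Dox), and 22Rv1-M4 cells with a scramble or a galectin-4 knockdown. Scanner software, background settings and the tools behind the values are not given in the sources used here.

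The authors deposited a non-normalized table with the intensity of each of 47303 probes on each array, on a linear scale, beside a detection p-value for each probe and array. Its lowest intensities lay between 83.7 and 90.9 per array, so no background had been subtracted, and it held no negative control probes. A deposited matrix of log2 values had nearly equal medians on all arrays (6.80 to 6.81). Of its 851454 values, all but 114, in 25 probes, lay within 0.01 of quantile-normalized log2 intensities computed from the first table without background correction; the largest difference was 1.82. The non-normalized intensities were used for the main results and the log2 matrix as an alternative.

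Intensities were background-corrected and normalized with neqc in limma 3.58.1 (R 4.3.3, statmod 1.5.0): a normexp background estimated from the detection p-values, an offset of 16 and quantile normalization. The offset shrinks fold changes of dim probes, background correction widens them, and quantile normalization assumes that arrays share 1 distribution of values, so changes are relative to the bulk of genes on an array. Of the probes, 30103 carried 1 gene symbol, 8 carried several and 17192 carried none. The last 2 kinds were not analysed. Symbols were looked up by Entrez ID for 30064 probes in a RefSeq table of assembly GRCh38.p14, used for names and for the order of genes along chromosomes, and 0 changed. Probes with a detection p-value under 0.05 on at least 3 arrays were kept (25675, of which 18408 named). The probe with the highest mean represented each gene, which gave 13680 genes. Bead arrays give no counts, so the number of arrays limits the precision.

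A single limma model with 6 group means was fitted to all arrays (12 residual degrees of freedom, 8.73 prior degrees of freedom). Contrasts compared Dox with no Dox in 22Rv1 and in LNCaP, knockdown with scramble in 22Rv1-M4, both Dox responses with each other, and 22Rv1-M4 scramble with 22Rv1 without Dox. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 13680 genes, two-sided. Genes called the same way with Dox in both lines, and those among them called the opposite way in the knockdown, were counted beside the numbers that independent lists would give. Gene lists, 36 in number, covering pathways, gene families and markers of cell types, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with LGALS4 left out. Camera with an estimated correlation and fry were run beside it.

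Groups, contrasts, lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule took LGALS4, then in each comparison the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap between groups, up to 4 members of a list, up to 10 shared genes per direction by p-value, and the 5 largest differences between lines in each direction. It also allowed, among others, KLK3, EGFR, ERBB2, ERBB3, IGF1R, C1GALT1, CDH1, SNAI2 and MYC whether called or not. The probe for IGF1R did not pass the detection filter, so this gene was not tested. A fold against a group in which the probe was above background on none of the 3 arrays is given as a lower bound. Such a bound rests on the mean of the other group and leaves out the spread between its arrays.

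The limma model and camera were tested on simulated log2 values in which 200 of 13680 genes were changed, in 10 data sets per comparison. Background correction, normalization between arrays, the detection filter and the choice of probe were not part of this test. At a true change of 1.5-fold, 44.2% of the changed genes were recovered for 22Rv1 Dox, 43.6% for LNCaP Dox, 47.2% for the knockdown and 43.7% for 22Rv1-M4 against 22Rv1. At 2-fold, these were 96.3%, 96.0%, 96.7% and 96.9%. False calls made up 4.30%, 4.49%, 4.42% and 5.60% of the calls. A list of 30 genes shifted by 0.5 on the log2 scale was called by camera in 20 of 20 data sets made for 22Rv1 Dox, and no other list was. Simulated genes varied independently of each other, without correlation within lists or shared variation between arrays. The rates of false calls therefore do not cover correlated genes and lists as in the real data. Far fewer genes were changed than the 24.8% called in 22Rv1 Dox. The share recovered depends on how many genes change, so it need not hold for the real comparisons.

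Alternatives changed the background correction, the normalization between arrays, the detection filter, the source of values, the probe for a gene, the arrays in the fit, the weights of arrays, a block for the replicate number and the variance model, and left out each array in turn. Array weights were estimated gene by gene because the default estimate did not converge. The files and labels give no slides, so a block for slides was not run. The axis of largest variation within groups (the first principal component of deviations from group means) was taken out of every array as an alternative added after the data were seen. Fits after that step kept the same degrees of freedom, so their p-values may be too small and their counts of calls too high. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.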

Results

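Gene expression was measured on 18 arrays of human prostate cancer cells, 3 in each of 6 groups. The series asked how the RNA of these cells changes when galectin-4 is forced or lowered. Galectin-4, encoded by LGALS4, is a lectin that binds galactose-containing sugars and is made mainly in the epithelium of the digestive tract. LNCaP and 22Rv1 are established prostate cancer cell lines. Cells of each line held a galectin-4 construct under a tetO promoter, which doxycycline (Dox) switches on, and were measured without and with Dox. Another cell line, 22Rv1-M4, was measured with a scramble knockdown and with a galectin-4 knockdown (shGal4). No group received Dox without the construct.

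Mean intensity per array lay between 306 and 404, and 19798 to 21317 of 47303 probes (41.9% to 45.1%) were above background on an array. Within groups, r between arrays ranged from 0.976 to 0.996. The median SD of a gene was 0.10 on the log2 scale in 22Rv1 without Dox, 0.21 in 22Rv1 with Dox, 0.16 and 0.13 in LNCaP without and with Dox, and 0.18 and 0.15 in 22Rv1-M4 with scramble and knockdown. A single axis held 24.8% of the variation within groups. RLN2, AGR2, PRKCB, RNY4, MRPL47 and ANKRD37 were among the genes that lay high on it, and MT1M lay low. Small RNAs other than RNY4 (VTRNA1-1, SNORD13, SNORD3C, RNU4ATAC and MIR98) and ribosomal protein genes (RPL36A, RPS7 and RPL34) also lay high. On this axis 22Rv1 Dox replicates 2 and 3 lay at 23.1 and -25.4 from their group mean, and M4 scramble replicate 3 at 17.8. Between groups, the mean score was -18.3 in 22Rv1 without Dox and -4.88 with Dox, -7.67 in LNCaP without Dox and 25.5 with Dox, and 9.75 in M4 scramble and -4.33 in the knockdown. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

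LGALS4, read by 1 probe, had a mean log2 level of 12.44 ± 0.03 (SD, n = 3) in M4 scramble cells and 5.00 ± 0.29 in the knockdown, a change of -7.45 (SE 0.21, adjusted p = 5.17e-16 by limma, 175-fold lower in 3 of 3 arrays). In LNCaP the level was 4.58 ± 0.05 without Dox, not above background on any of 3 arrays, and 6.49 ± 0.67 with Dox. That rise of 1.92 (SE 0.21, adjusted p = 1.06e-05) was at least 3.41-fold by the mean of the 3 Dox arrays, which lay at 5.73, 6.79 and 6.96. In 22Rv1 the LGALS4 level was 5.90 ± 0.06 without Dox and 5.84 ± 0.16 with Dox, a change of -0.06 (SE 0.21, adjusted p = 0.874), so that a rise with Dox was not detected there. The responses of both lines differed by -1.98 (SE 0.30, adjusted p = 1.11e-04). Before background correction, mean intensity in LNCaP was 112 without and 176 with Dox. In 22Rv1 it was 161 without and 151 with Dox, against 6160 in M4 scramble cells.

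**Figure D1:**
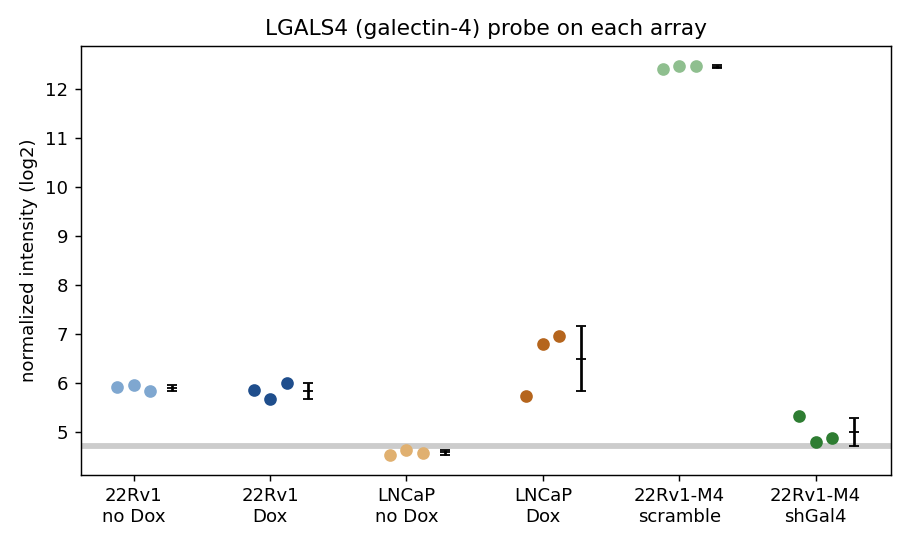
Normalized log2 intensity of the LGALS4 probe on each of the 18 arrays; dots are arrays, horizontal ticks group means, bars the SD of 3 arrays, and the grey line marks the level near which the probe is no longer above background. M4 scramble cells average 12.44, the knockdown 5.00, and LNCaP cells rise from 4.58 to 6.49 with Dox while 22Rv1 cells stay at 5.90 and 5.84.

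In 22Rv1 cells with Dox, the gene ERBB2, which encodes the receptor tyrosine kinase HER2, rose 6.70-fold (log2 change 2.74, SE 0.14, adjusted p = 8.89e-12). ITGA5, a subunit of the fibronectin receptor, rose by 3.21 on the log2 scale (SE 0.18), CHRD, an antagonist of bone morphogenetic proteins, by 3.00 (SE 0.12), and BASP1 by 3.42 (SE 0.33). CRYAB, a small heat shock protein, rose at least 5.58-fold. PRKCB (3.15), ANKRD37 (3.08) and the small RNA RNY4 (3.68), which lay high on the within-group axis, also rose, as did POU3F2, a neural transcription factor (2.64), and CMKLR2 (2.52). ALB, the gene of serum albumin, fell 47.2-fold (log2 change -5.56, SE 0.17, adjusted p = 1.65e-15), and its second probe changed by -6.16. CDH2, which encodes N-cadherin, fell by 4.19 (SE 0.18), CBLN2 by 4.34 (SE 0.21), TMEFF2 by 3.61 (SE 0.25) and AKR1C2, a steroid-reducing enzyme whose probe may also read its paralogs, by 5.01 (SE 0.15). COLCA1 fell at least 6.98-fold and HLA-DQB1, from a family of similar genes, at least 7.62-fold. FGL1 fell at least 8.31-fold and SYTL2 and PON1 fell by 3.53 and 3.04, but the second SYTL2 probe changed by -0.09 and 4 other FGL1 probes by -0.89, -1.29, 0.09 and -2.57. Each of these genes separated 3 of 3 Dox arrays from 3 of 3 controls, as the rule that picked them required. Called genes numbered 3394 (1250 higher, 2144 lower), 24.8% of 13680. By at least 2-fold, 391 rose and 264 fell.

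Hypoxia and glycolysis genes rose in 22Rv1 with Dox: 24 of 36 were higher and 0 lower (25 and 0 adjusted over the list alone), with a median log2 change of 0.76 (camera adjusted p = 4.89e-17; adjusted p = 0.0808 with an estimated correlation). They included BNIP3, which encodes a mitochondrial membrane protein (1.84), and ANKRD37 (3.08). Of 34 genes of the G1/S phase, 18 fell and 1 rose (20 and 2 adjusted over the list alone), among them the replication helicase subunits MCM2 (-1.12) and MCM5 (-1.06). The list's camera adjusted p was 1.76e-04 (adjusted p = 0.462 with an estimated correlation). The unfolded protein response list fell too, with 11 of 21 genes lower and 2 higher (the same 11 and 2 adjusted over the list alone; camera adjusted p = 1.76e-04; adjusted p = 0.368 with an estimated correlation). The endoplasmic reticulum proteins CRELD2 (-1.22) and MANF (-1.08) fell, and XBP1, a transcription factor of this response, rose (0.74). Cholesterol synthesis genes fell in 12 of 20 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 5.89e-04; adjusted p = 0.136 with an estimated correlation), with LSS (-1.47) and NSDHL (-0.95) lower and HSD17B7 (1.60) higher.

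Genes typical of intestinal epithelium fell in 22Rv1 with Dox in 8 of 15 cases and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 7.46e-04; adjusted p = 0.0512 with an estimated correlation). CDH17, an intestinal cadherin (-2.32), and VIL1, villin (-1.59), fell, and the secreted trefoil peptide TFF2 rose (1.59). Metallothioneins are small zinc-binding proteins, and their list also held a gene that is not a metallothionein. Genes of this list fell in 7 of 9 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00841, adjusted p = 0.462 with an estimated correlation). MT1H (-2.71) and MT1F (-2.07), whose probes may read other metallothioneins, fell, while MT3 rose at least 4.14-fold. Of 19 targets of the oxidative stress factor NRF2, 8 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.342 with an estimated correlation). AKR1C2 (-5.01) and the transporter ABCC2 (at least 1.83-fold) fell and GCLM, a subunit of the glutathione-synthesizing ligase, rose (1.76). Histone genes fell in 9 of 26 cases and rose in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.00241; adjusted p = 0.462 with an estimated correlation), including H2AC20 (-1.11) and H2AC18 (-1.18). All 8 lists kept camera's call after the within-group axis was taken out. Without 22Rv1 Dox replicate 3, 4246 genes were called and camera's adjusted p was 0.0552 for metallothioneins and 0.0557 for histones (over all of camera's alternatives, 0.00172 to 0.462 and 1.91e-05 to 0.462); array weights called 5637 genes.

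In LNCaP cells with Dox, 334 genes rose and 58 fell by at least 2-fold, and 4 rose and 0 fell by at least 4-fold (42 and 55 in 22Rv1). PRKACB, a catalytic subunit of protein kinase A, rose by 2.14 on the log2 scale (SE 0.18, adjusted p = 1.50e-06), and its 3 other probes by 0.83, 2.11 and 1.43. NAT1, an arylamine acetyltransferase, rose by 2.41 (SE 0.25), the hormone gene RLN2 by 1.96 (SE 0.30), the selenium carrier SELENOP by 1.90, RWDD3 by 1.96, TRAPPC13 by 1.89 and the histone gene H2AC6 by 1.91. RLN2 lay high on the within-group axis. TVP23C (2.59) and TVP23B (2.10) rose together, but their sequences are alike. ID1, an inhibitor of differentiation factors, rose by 1.84, while its second probe changed by 0.36, and with the within-group axis taken out it was not called (adjusted p = 0.069). BHLHE40, a transcriptional repressor, fell by 1.59 (SE 0.18, adjusted p = 1.06e-05), the glycolytic enzyme ENO2 by 1.47 (SE 0.19), the secreted glycoprotein STC1 by 1.40 (SE 0.14) and the scaffold AKAP12 by 1.46 (SE 0.15; other probes -0.93 and -0.21). SLC6A10P changed by -1.40, and the like sequences VCX3B, VCX3A and VCX by -1.49, -1.47 and -1.41, though a second VCX3A probe changed by 0.03. COXFA4L2 changed by -1.46 (SE 0.24) and the metallothionein MT1H by -1.40 (SE 0.27), though a second MT1H probe changed by -0.03. In each of these genes 3 of 3 Dox arrays lay apart from 3 of 3 controls, as the rule that picked them required. Called genes numbered 3809 (1489 higher, 2320 lower), 27.8% of 13680.

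Hypoxia and glycolysis genes fell in LNCaP with Dox: 19 of 36 were lower and 2 higher (23 and 2 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 1.69e-05; adjusted p = 0.733 with an estimated correlation). ENO2 (-1.47) and GPI (-1.30), enzymes of glycolysis, were among them. Of 52 genes of the G2/M phase, 27 fell and 5 rose (29 and 7 adjusted over the list alone; camera adjusted p = 0.00579; adjusted p = 0.733 with an estimated correlation). The mitotic kinase AURKA (-0.94) and the spindle protein NUSAP1 (-0.82) fell and CKS1B, a partner of cyclin-dependent kinases, rose (0.54). Fatty acid synthesis genes fell in 13 of 21 cases and rose in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 0.00789; adjusted p = 0.733 with an estimated correlation), with the desaturase FADS1 at -0.67. Genes of the mitochondrial ribosome rose in 23 of 67 cases and fell in 7 (25 and 9 adjusted over the list alone; camera adjusted p = 0.00214; adjusted p = 0.733 with an estimated correlation), such as MRPL47 (1.75), which lay high on the within-group axis, MRPS33 (1.09) and, lower, MRPL37 (-0.66). Histone genes rose in 12 of 26 cases and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 3.02e-06; adjusted p = 0.733 with an estimated correlation), H2AC6 by 1.91 and H2AC25 by 1.32.

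The LNCaP change followed the within-group axis across genes (r = 0.66 between loading and log2 change, over genes, which are not independent replicates). After that axis was taken out, 2531 genes were called, hypoxia and glycolysis (adjusted p = 2.45e-05), G2/M (2.89e-04) and histones (0.0259) kept camera's call, and fatty acid synthesis (0.402) and the mitochondrial ribosome (0.530) lost it. The excess of falls over rises also depended on these choices: 39.1% of called genes were higher in the main result, 47.8% with the axis taken out and 48.5% of the 2213 called with median scaling in place of quantile normalization. Without LNCaP Dox replicate 3 the G2/M list had an adjusted p of 0.0608. The fatty acid list had 0.0541 with the mean of a gene's probes. Over all of camera's alternatives the highest adjusted p of each of the 5 lists was that with an estimated correlation, and the lowest lay between 6.95e-08 (histones) and 8.03e-04 (fatty acid synthesis).

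In 22Rv1-M4 cells, KRT19, a keratin of simple epithelia, rose 38.3-fold in the galectin-4 knockdown (log2 change 5.26, SE 0.15, adjusted p = 5.40e-16). EDN2, the vasoconstrictor peptide endothelin 2, rose by 3.40 (SE 0.14), HLA-DQB1, which encodes a major histocompatibility complex chain and has similar paralogs, by 3.18 (SE 0.16), INMT at least 5.43-fold and SERTAD4 also at least 5.43-fold. TARP rose at least 12.6-fold, with an SD of 1.26 among the 3 knockdown arrays. BASP1 (4.11), CGA, the hormone alpha chain (4.10), DIO2, a deiodinase of thyroid hormone (3.60), and IER3 (3.30) rose as well, with SDs of 1.16, 1.68, 1.57 and 1.63 among the 3 knockdown arrays. GP2, a zymogen granule glycoprotein, fell at least 64.9-fold (adjusted p = 5.63e-19), NPTX2, a neuronal pentraxin, at least 23.6-fold, and LGALS2, which encodes galectin-2, at least 16.6-fold. GSTA1, a glutathione transferase, fell by 3.89 (SE 0.15), and its other probes, which may read paralogs, changed by -3.96 and -3.40. Each of these genes separated 3 of 3 knockdown arrays from 3 of 3 scramble arrays, as the rule that picked them required. Called genes numbered 3193 (1780 higher, 1413 lower), 23.3% of 13680, and 230 rose and 349 fell by at least 2-fold.

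Genes of the metallothionein list, which also holds a gene that is not a metallothionein, fell in the knockdown in 9 of 9 cases (9 adjusted over the list alone). Their median log2 change was -4.64 (camera adjusted p = 3.38e-16, adjusted p = 0.036 with an estimated correlation). MT1G fell by 5.63 (SE 0.40, adjusted p = 1.25e-09), MT1E by 4.92 and MT2A by 4.64. MT1H, MT1F and MT1X fell too, but were not above background on 2, 2 and 1 of the 3 knockdown arrays. The MT1 and MT2A sequences are alike, so the probes may share signal, and a second MT1H probe changed by -0.50. Knockdown arrays also differed from each other in these genes, with an SD of 1.47 for MT1G against 0.35 in scramble cells. MT1E, MT1F, MT1G, MT1H, MT1X and MT2A were also lower on every Dox array than on every control array, in LNCaP as in 22Rv1. They thus fell both with Dox and in the knockdown. In LNCaP, MT1M and MT3 did not separate the arrays in this way, and camera did not call the list. Among 23 genes of epithelial adhesion, 9 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 3.57e-04; adjusted p = 0.269 with an estimated correlation): KRT19 and GRHL2, an epithelial transcription factor (1.49), rose and the keratin KRT8 fell (-0.63). Cholesterol synthesis genes fell in 10 of 20 cases and rose in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.173 with an estimated correlation), with HMGCS1 (-2.22) and SQLE (-1.15), enzymes early in the pathway, lower and TM7SF2 (0.71) higher. Of 28 enzymes that build or sialylate O-glycans, the sugar chains that galectins can bind, 7 fell and 3 rose (11 and 5 adjusted over the list alone; camera adjusted p = 0.0386; adjusted p = 0.133 with an estimated correlation). The sialyltransferases ST6GALNAC1 (at least 9.51-fold) and ST6GAL1 (-1.82) fell and ST3GAL4 rose (1.12). All 4 lists kept camera's call with the within-group axis taken out, but the O-glycan list's adjusted p was 0.0877 without M4 scramble replicate 2 and 0.123 without knockdown replicate 3 (0.0188 to 0.133 over all of camera's alternatives). Median scaling called 1926 genes, of which 34.9% were higher, against 55.7% in the main result.

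**Figure D2:**
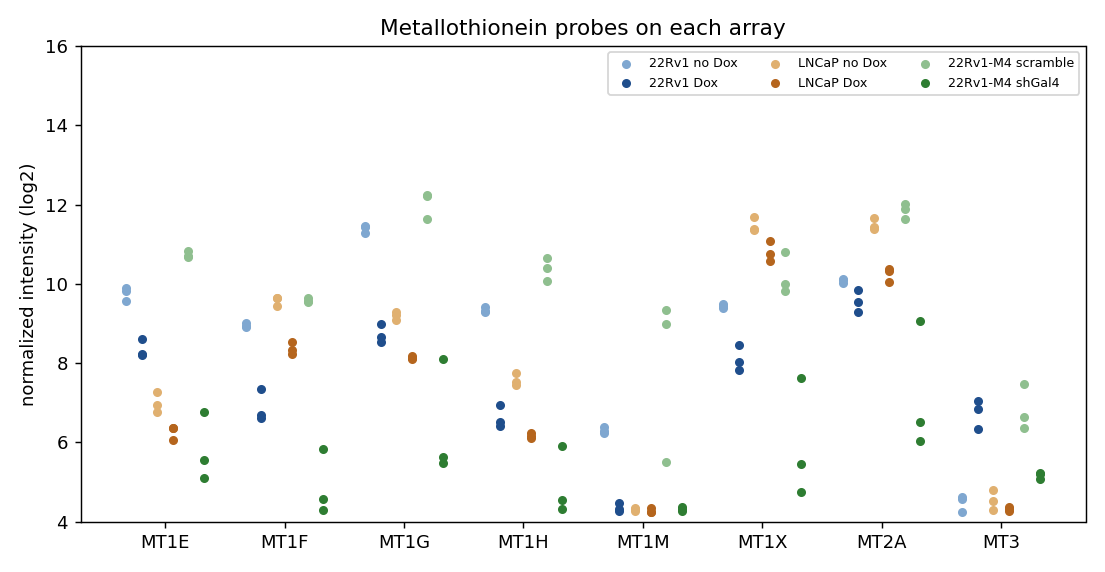
Normalized log2 intensity of 8 metallothionein probes on each of the 18 arrays, coloured by group (dots are arrays). In 22Rv1-M4 cells MT1G averaged 12.03 with scramble and fell by 5.63 in the knockdown, whose arrays spread over an SD of 1.47; sequences of this family are alike, so probes may share signal.

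Among the genes that could be named whether called or not, C1GALT1, the synthase of the core of most O-glycans, rose with Dox in LNCaP (1.13, adjusted p = 6.38e-04), changed by 0.60 in 22Rv1 (adjusted p = 0.0331, a call lost with median scaling, without background correction, where it was 0.23, without a detection filter, in a fit to only the arrays compared and, at an adjusted p of up to 0.244, without 22Rv1 Dox replicates 1 or 2 or any of the 3 controls) and fell in the knockdown (adjusted p = 0.00103). ERBB2 rose in the knockdown too (1.43, adjusted p = 1.07e-07), as it had with Dox in 22Rv1, and was -0.39 in LNCaP (adjusted p = 0.0383, a call lost, at an adjusted p of up to 0.0972, without any one of the 6 LNCaP arrays, with median scaling, with the replicate block and with the within-group axis taken out, where it was -0.067 with an adjusted p of 0.672). EGFR fell in LNCaP (-1.17, adjusted p = 2.33e-04), with 0.42 in 22Rv1 (adjusted p = 0.104) and -0.23 in the knockdown (adjusted p = 0.405), both of which were called with array weights or with the within-group axis taken out. SNAI2, a transcription factor of epithelial-mesenchymal transition, fell in 22Rv1 (at least 1.64-fold, adjusted p = 1.46e-06) and was 0.51 in LNCaP (adjusted p = 0.00789, but 0.0507 without LNCaP control replicate 3 and 0.0595 without Dox replicate 2). The genes KLK3 (prostate-specific antigen), CDH1 (E-cadherin), ERBB3 and MYC changed by at most 0.58 on the log2 scale in any of the 3 comparisons in the main result. Among them, KLK3 was called in LNCaP (0.39, adjusted p = 0.0297) and ERBB3 in the knockdown (0.58, adjusted p = 0.0311), and both calls were lost with median scaling and in a fit to only the arrays compared. That of ERBB3 was also lost with the mean of its probes (0.17, adjusted p = 0.309), array weights (0.31, 0.0825), the replicate block (0.0513), no detection filter (0.0556) and without the 3 arrays farthest out on the axis (0.0551). KLK3 also lost its call without LNCaP control replicates 1 or 2 or Dox replicates 2 or 3 (adjusted p up to 0.177), and ERBB3 without scramble replicates 2 or 3 or knockdown replicate 3 (up to 0.174). CDH1 was called without 22Rv1 Dox replicate 3 in 22Rv1 (adjusted p = 0.0328) and, in the knockdown, without scramble replicate 3 (0.0461), with array weights (-0.57, 0.00336) and with the axis taken out (-0.74, 5.3e-05). ERBB3 in LNCaP was called in a fit to only the arrays compared (-0.43, 0.0133) and with array weights (-0.42, 0.0181).

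**Figure D3:**
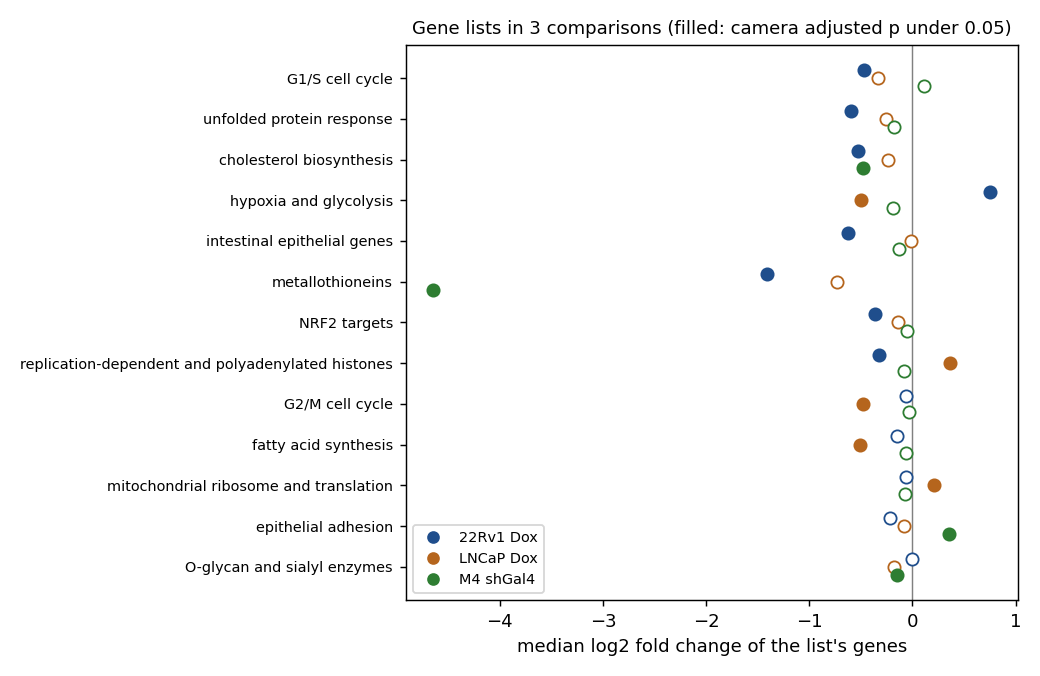
Median log2 fold change of the genes of 13 lists (horizontal axis) in 22Rv1 with Dox, LNCaP with Dox and the M4 knockdown; filled circles had a camera adjusted p under 0.05 with the preset correlation. Hypoxia and glycolysis genes lie at 0.76 in 22Rv1 and -0.50 in LNCaP, and metallothioneins at -4.64 in the knockdown, the only filled circle of the 3 comparisons that held with an estimated correlation.

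The 22Rv1 and LNCaP responses to Dox differed in 2572 of 13680 genes (1288 with a higher log2 change in 22Rv1, 1284 with a lower one). ITGA5 changed by 3.21 in 22Rv1 and -0.57 in LNCaP, a difference of 3.77. ERBB2 differed by 3.14 (SE 0.19, adjusted p = 6.52e-10), BHLHE40, which rose by 1.54 in 22Rv1 and fell by 1.59 in LNCaP, by 3.13, BASP1 by 3.19 and CMKLR2 by 3.22. ALB (-5.32), AKR1C2 (-4.87), CDH2 (-4.13), TMEFF2 (-3.78) and AGR2, a secretory pathway disulfide isomerase (-3.75), differed the other way. AGR2, which lay highest on the within-group axis, changed by -2.38 in 22Rv1 and 1.37 in LNCaP. For hypoxia and glycolysis, 31 of 36 genes had a higher response in 22Rv1 and 0 a lower one (camera adjusted p = 9.58e-24; adjusted p = 0.0256 with an estimated correlation). Intestinal epithelial genes had a lower response in 22Rv1 in 8 of 15 cases and a higher one in 2 (camera adjusted p = 7.81e-04; adjusted p = 0.0256 with an estimated correlation), and histones in 18 of 26 and 0 (camera adjusted p = 1.16e-09; adjusted p = 0.115 with an estimated correlation). Median scaling called 1707 genes, of which 38.5% had a higher response in 22Rv1 against 50.1% in the main result, and array weights called 4114.

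Despite these differences, more genes moved the same way with Dox in both lines than independent lists would give: 202 rose in both against 136 expected, and 585 fell in both against 364. In opposite directions, 219 rose in 22Rv1 and fell in LNCaP against 212 expected, and 81 fell in 22Rv1 and rose in LNCaP against 233. Across genes, which are not independent replicates, log2 changes of both lines had r = 0.107 and rho = 0.191, and 59 of 100 splits of the arrays gave an r as large or larger in size. For 22Rv1 Dox and the knockdown r was -0.138 (34 of 100 splits) and for LNCaP Dox and the knockdown -0.170 (63 of 100). The count of 787 shared genes was 467 without 22Rv1 Dox replicate 2, 1516 without replicate 3, 520 without replicate 1, 506 and 493 without 22Rv1 control replicates 1 and 3, and 469 without LNCaP Dox replicate 3. Median scaling gave 323.

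Of the 787 shared genes, 226 changed the opposite way in the knockdown, although LGALS4 itself was flat in 22Rv1: 57 rose with Dox in both lines and fell in the knockdown (14.1 expected from independent lists), and 169 fell with Dox and rose in the knockdown (47.3 expected). Rising with Dox were STT3B, a catalytic subunit of the enzyme that attaches N-glycans (0.85 in 22Rv1, 0.99 in LNCaP and -1.18 in the knockdown), CFD, complement factor D (1.58, 1.05 and -0.89) and IFRD1 (0.88, 1.14 and -0.99). Falling with Dox were TNFRSF19, a tumour necrosis factor receptor family member (-1.14, -0.95 and 1.57), SLX4IP (-1.91, -1.38 and 0.88), ST7 (-0.74, -0.72 and 1.45) and CBLN2 (-4.34, -1.03 and 2.60). The junction genes MARVELD2 (-0.96, -0.79 and 0.93) and JUP, plakoglobin (-0.81, -0.59 and 0.87), fell by their brightest probe, but the mean of their probes was not called in LNCaP. Of the 226 genes, 95.1% loaded on the within-group axis in the direction of their Dox change. With that axis taken out 149 genes met the count, 87 of them among the 226, and median scaling gave 46, with 23 in each direction. The count was 134, 143 and 140 without 22Rv1 control replicates 1, 2 and 3, 140 and 571 without 22Rv1 Dox replicates 1 and 3, 147 without LNCaP control replicate 1, 130 without LNCaP Dox replicate 3 and 137 without knockdown replicate 1.

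**Figure D4:**
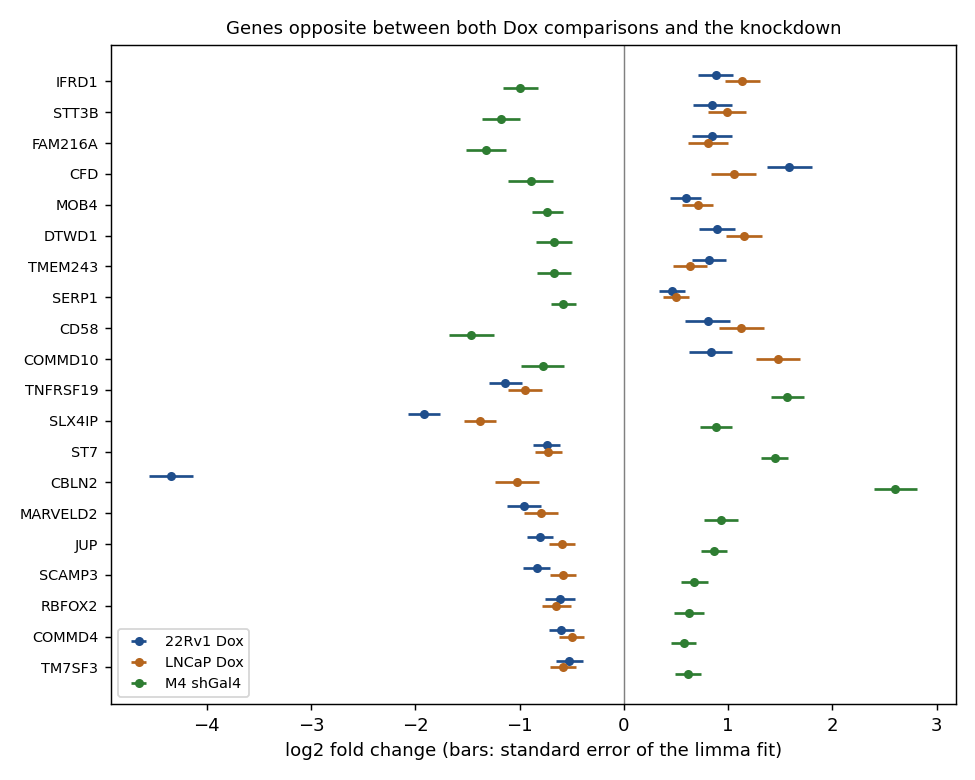
Log2 fold changes of the 10 genes per direction with the smallest p-values among those that changed one way with Dox in both lines and the opposite way in the knockdown; points are limma estimates from 3 arrays per group and bars their standard errors. CBLN2 shows the widest range, from -4.34 in 22Rv1 to 2.60 in the knockdown.

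22Rv1-M4 scramble cells were also compared with 22Rv1 cells without Dox, although the cells carried different vectors, so that line and vector cannot be told apart. LGALS4 was 93.2-fold higher in M4 (log2 difference 6.54, SE 0.21, adjusted p = 2.41e-15). Higher in M4 were GP2 (at least 66.7-fold), PPP1R1B, a phosphatase inhibitor (5.96, SE 0.14), the cancer-testis antigen MAGEC2 (at least 27.7-fold), DAPL1 (5.01) and GSTA1 (at least 28.2-fold, with like paralogs). Lower in M4 were IGFBP3, a carrier of insulin-like growth factors (-4.86, SE 0.23), CRIP1 (-4.67), CLDN11, a tight junction claudin (-4.60), the growth factor gene HGF (at least 13.5-fold) and KRT19 (-4.01, SE 0.15). In each of them 3 of 3 arrays lay apart from 3 of 3, as the rule that picked them required. In all, 4849 genes differed (2016 higher in M4, 2833 lower), 35.4% of 13680. Genes of the mitochondrial ribosome were higher in M4 in 28 of 67 cases and lower in 3 (28 and 5 adjusted over the list alone; camera adjusted p = 0.00101; adjusted p = 0.81 with an estimated correlation; 0.153 with the within-group axis taken out). Genes of the metallothionein list were higher in 5 of 9 cases, among them MT3 (at least 4.39-fold) and MT2A (1.76), and lower in 1 (6 and 1 adjusted over the list alone). The list's camera adjusted p was 0.0269, and 0.81 with an estimated correlation. Without M4 scramble replicate 2 the list's camera adjusted p was 0.0808, and with the strict filter 0.0511.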

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

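The test of the LGALS4 probe was chosen only after the result was seen. So were the counts without single Dox arrays as a test of an aberrant array, and the share of cells that the 10 largest falls would need. The same holds for tests with the within-group axis taken out, and for lists under settings other than an estimated correlation, fry and the replicate block. The readings of 2 other tests, named where they stand, were also made only then. All results here share 1 reason to look closer: the response to Dox differed between 22Rv1 and LNCaP by limma's test of the difference itself. That was so in 2572 genes, and 3 of 100 drawn splits of the arrays within both lines, the real one included, gave as many (the highest other split gave 3094). Such splits ask whether Dox changed genes in either line, not whether both responses were equal. No conclusion on chance is therefore drawn from them. Values below are log2 responses in 22Rv1 minus those in LNCaP.

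LGALS4 itself differed by -1.98, being flat in 22Rv1 and higher by 1.92 (SE 0.21) with Dox in LNCaP, which argues against a probe blind to every forced transcript, but the construct's sequence is not given in the sources used here and the LNCaP rise may come from the cells' own gene. Of 814 genes called in opposite directions in LNCaP Dox and the knockdown, 73.0% (95% exact binomial interval 69.8 to 76.0) went the LNCaP way in 22Rv1, which met the bound of over 60% set beforehand against a missing forced transcript. That bound is held to be wrong, a reading made only after the value was seen, because Dox itself could move these genes in both lines (no group had Dox without the construct) and 95.7% of them load on the within-group axis in their LNCaP direction; with the axis taken out the share was still 66.4% (61.9 to 70.7) of 467 genes. Genes are not independent replicates, so neither binomial interval measures the spread between arrays or cultures. A forced transcript that the probe misses and a forced transcript that was not made in these 22Rv1 cultures therefore cannot be told apart. A response of the cells to forced galectin-4, the biological explanation the design names, stays open as untested.

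Large changes in 22Rv1 stood beside that flat LGALS4: 3394 genes were called (1 of the 10 splits of the 6 arrays gave as many, the highest other gave 0, and 10 splits are too few for a share under 0.05). A single aberrant Dox array as the whole source is argued against, since 2608, 2576 and 4246 genes were called without Dox replicates 1, 2 and 3, of which 2482, 2361 and 3118 had also been called in the same direction with all arrays. LNCaP cells mixed into the Dox cultures may account for small rises, as 50 genes high in LNCaP and not above background in 22Rv1 gained a median of 1.13% of their LNCaP signal (quartiles -0.52 and 3.74), but the 10 largest falls would need at least 87.8% of the cells replaced. The medians of windows of 50 neighbouring genes varied 1.59 times as much as in shuffled order, more than in any of 1000 shuffles. That met the bound of over 1.5 set beforehand for chromosome segments that differ between clones. LNCaP Dox (1.51) and the knockdown (1.90) met it too. M4 against 22Rv1 controls (1.40) did not, and 22Rv1 Dox with the axis taken out (1.497) fell just short of it. LNCaP against 22Rv1 controls, 2 different lines, gave 2.12. Given these values clones stay open and are not read as shown, again decided only after the values were seen. Clones or passages, Dox itself and forced galectin-4 cannot be told apart here.

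ITGA5 (3.77), CMKLR2 (3.22), BASP1 (3.19), ERBB2 (3.14) and BHLHE40 (3.13) had the largest differences upward, and ALB (-5.32), AKR1C2 (-4.87), CDH2 (-4.13), TMEFF2 (-3.78) and AGR2 (-3.75) the largest downward. EGFR differed by 1.59 and SNAI2 by -1.69.

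List medians differed by 1.34 for hypoxia and glycolysis (BNIP3 1.88, PFKFB4 2.53), 0.24 for G2/M (TMPO 1.48, CENPF 1.25) and 0.35 for fatty acid synthesis (ACSL1 2.12, ELOVL7 1.34). They were lower in 22Rv1 by -0.43 for cholesterol synthesis (HSD17B7 2.49, LSS -1.14, SC5D -1.50), -0.41 for markers of prostate luminal cells (SPDEF 1.54, KLK2 1.33, SLC45A3 -2.19, FOLH1 -2.68), -1.23 for intestinal epithelial genes (TFF2 1.49, TFF3 0.63, CDH17 -2.29, VIL1 -1.59), -0.31 for NRF2 targets (GCLM 2.31, ME1 0.62, AKR1C3 -2.01) and -0.95 for histones (H2BC5 -1.91, H2AC6 -2.24). Nuclear-encoded oxidative phosphorylation genes differed by -0.22 (UQCRH -0.66, COX6A1 -0.69) and genes of the mitochondrial ribosome also by -0.22 (MRPL10 0.73, MRPS25 0.71, MRPL11 -0.96, MRPS22 -0.92). With an estimated correlation 2 of these 10 lists held, hypoxia and glycolysis and intestinal epithelial genes; the other 8 had an adjusted p of at least 0.115. Median scaling cost cholesterol synthesis (adjusted p = 0.140), oxidative phosphorylation (0.137) and luminal markers (0.0765) their calls, and taking out the within-group axis cost the mitochondrial ribosome its call (0.311). Over all of camera's alternatives the adjusted p ranged from 0.0114 to 0.441, 0.00532 to 0.542, 0.0241 to 0.142 and 0.00529 to 0.655 for these 4 lists. The replicate block cost cholesterol synthesis (0.0613) and the gene ME1 (0.0534) their calls.

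Single arrays decided some of these calls. Cholesterol synthesis was not called without 22Rv1 control replicate 3, 22Rv1 Dox replicates 1 or 2, any of the LNCaP controls or LNCaP Dox replicate 1 (adjusted p 0.0521 to 0.085). Oxidative phosphorylation was not called without 22Rv1 Dox replicate 1, LNCaP control replicates 2 or 3 or LNCaP Dox replicate 1 (0.0526 to 0.0648), and the mitochondrial ribosome without 22Rv1 Dox replicates 1 or 3, LNCaP control replicate 2 or LNCaP Dox replicate 1 (0.0526 to 0.152). Luminal markers lost the call without 22Rv1 Dox replicates 1 or 2, LNCaP control replicate 3 or LNCaP Dox replicate 3 (0.0526 to 0.0624), NRF2 targets without 22Rv1 Dox replicate 2 (0.0624) or LNCaP control replicate 3 (0.05004), and G2/M without LNCaP Dox replicate 3 (0.0559). Calls for UQCRH, COX6A1, MRPL10, MRPS25 and ME1 were lost with median scaling. UQCRH and MRPL10 also lost the call with the mean of probes (adjusted p = 0.118 for each), and MRPS25 lost it without a detection filter (0.0510). ME1 lost it without background correction and with the deposited log2 matrix (0.23, adjusted p = 0.223 in each). It also lost it without a detection filter (0.0561), in a fit to only the arrays compared (0.0554) and with the other variance model (0.0536). COX6A1 also lost it without 22Rv1 Dox replicate 3 (0.0508), MRPL10 without 22Rv1 control replicate 2, 22Rv1 Dox replicate 3, LNCaP control replicates 1 or 2 or LNCaP Dox replicate 3 (up to 0.0727), and MRPS25 without 22Rv1 control replicates 1 or 3, 22Rv1 Dox replicate 1, LNCaP control replicates 1 or 3 or LNCaP Dox replicate 2 (up to 0.114). ME1 lost it without any one array but 22Rv1 control replicate 2, 22Rv1 Dox replicate 1 and LNCaP control replicate 3 (up to 0.13).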

How the results depend on the processing

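Taking out the within-group axis and leaving out the 3 arrays farthest out on it (which leaves 1 array of 22Rv1 Dox, assumed to vary like the other groups) were tests chosen only after the results were seen. So was running lists without single arrays or under settings other than an estimated correlation, fry and the replicate block. A block for slides was not run. Of named genes' values under settings chosen earlier, 2352 kept direction and side of the threshold, 51 lost the call, 5 gained it and 2 turned sign; without single arrays these were 1609, 63, 2 and 6. Of 29 called lists, 3 kept their call with an estimated correlation and 26 with fry, which does not compare a list with other genes, and 26 of the 27 tested did with the replicate block. Lists kept their call 215 times and lost it 17 times under added settings and 206 and 28 times without single arrays, and in none of these did a called list turn direction. Gene counts under settings not named here stayed within 1.5 times the main count.

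Median scaling in place of quantile normalization called 2213 genes in LNCaP Dox, 1926 in the knockdown, 1707 for the difference between lines, 323 for both Dox comparisons and 46 of these that were opposite in the knockdown. Under it the median of all genes lay at -0.15 in 22Rv1 Dox and -0.11 in LNCaP Dox, so changes are relative to that shift, and 25.3% of 2889 called genes were higher in 22Rv1, against 36.8%. Array weights called 5637 genes in 22Rv1 Dox, 4114 for the difference, 1912 for both and 614 opposite in the knockdown, and a fit to only the arrays compared gave 119 of the last. The axis taken out gave 2531 in LNCaP Dox, 512 for both and 149 opposite in the knockdown. These counts may be too high, since the fit counted no degrees of freedom for the axis. Without the 3 farthest arrays, 2866, 4848 and 3595 were called in 22Rv1 Dox, LNCaP Dox and the knockdown. Leaving out 1 array gave 2468 to 4246 genes in 22Rv1 Dox, 2542 to 3126 in LNCaP Dox, 2307 to 2869 in the knockdown, 1961 to 3171 for the difference, 467 (without 22Rv1 Dox replicate 2) to 1516 (without replicate 3) for both, 130 (without LNCaP Dox replicate 3) to 571 (without 22Rv1 Dox replicate 3) for those opposite in the knockdown, and 3918 to 4575 for M4 against 22Rv1. For all of these changes the cause was not tested.

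Camera called 8 lists in 22Rv1 Dox, 5 in LNCaP Dox, 4 in the knockdown, 10 for the difference and 2 for M4 against 22Rv1. With an estimated correlation these were 0, 0, 1, 2 and 0, and fry called 19, 14, 13, 16 and 15. Without a detection filter (20041 genes) 8 lists were called in LNCaP Dox and 8 in the knockdown, with the axis out 7 in the knockdown, and with the strict filter (11118 genes) 6 for the difference and 1 for M4 against 22Rv1. Leaving out 1 array gave 6 to 8, 5 to 7, 3 to 5, 6 to 11 and 1 to 3 lists. Replicate numbers did not pair arrays (r of deviations from -0.11 to 0.11), and as a block they gave 3080, 3553 and 2978 genes in 22Rv1 Dox, LNCaP Dox and the knockdown.

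Some named genes that were not called turned sign. With the axis out ERBB3 was 0.20 and MYC 0.077 in 22Rv1 Dox, ERBB3 0.18, CDH1 0.27 and MYC 0.17 in LNCaP Dox (from -0.43, -0.33 and -0.27), and MYC -0.049 in the knockdown. The mean of probes gave MYC 0.011 in 22Rv1 Dox, and array weights gave MYC -0.048 in the knockdown. Leaving out 1 array gave -0.14 to 0.020 for LGALS4, -0.027 to 0.0067 for KLK3, -0.27 to 0.16 for ERBB3 and -0.26 to 0.058 for MYC in 22Rv1 Dox and -0.041 to 0.23 for MYC in the knockdown. Signal near background limits LGALS4 in LNCaP without Dox and the genes given as bounds. With 200 simulated changed genes, 1.5-fold changes were recovered in 44.2% of cases for 22Rv1 Dox, which need not hold where more genes change.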

Other observations

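The tests that relate 22Rv1-M4 scramble cells to other comparisons, and those with the within-group axis taken out, were chosen only after the results were seen. Many genes that set M4 scramble cells apart from 22Rv1 cells moved back in the galectin-4 knockdown. FOXA2, a forkhead transcription factor of endoderm, was at least 6.15-fold higher in M4 and fell at least 5.98-fold in the knockdown. The sialyltransferase ST6GALNAC1 was at least 9.77-fold higher and fell at least 9.51-fold, and the galectin LGALS2 was higher by 4.16 on the log2 scale and fell at least 16.6-fold. The transporter ABCC3 was higher by 3.12 and fell by 2.90, and DPP4, a surface peptidase, was higher by 2.22 and fell by 2.20. AZGP1, a luminal secreted protein, was higher by 3.01 and fell by 1.72, and SCGN, a calcium-binding protein of neuroendocrine cells, was higher by 2.06 and fell by 2.53. In the other direction KRT19 was lower in M4 (-4.01) and rose by 5.26 in the knockdown, and CHGB, a granin of secretory granules, was lower (-2.14) and rose by 1.58.

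Of all genes called in both, 1704 went opposite ways and 183 the same way. Both comparisons use the M4 scramble arrays, so noise in these 3 arrays alone gives opposite signs and independent lists are no measure of what to expect. In 100 simulations without effects r across genes, which are not independent replicates, was -0.50 and the covariance -0.0140, against -0.554 and -0.163 measured. Thus r alone shows nothing beyond the shared arrays, while the covariance was larger than their noise gave. Any real difference of the shared group from both others would also enlarge the covariance. No conclusion on a return toward 22Rv1 levels is therefore drawn from a covariance above these simulations. For 22Rv1 Dox and M4 scramble cells, both compared with the same 22Rv1 control arrays, r was 0.487 against 0.50 in simulations and the covariance 0.140 against 0.0140, and of the genes called in both 1790 went the same way and 215 the opposite way. A state peculiar to the shared control cultures would enter both comparisons of each pair and was not tested.

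Some genes of lists that camera did not call changed. In the knockdown, 7 of 15 stemness genes fell and 1 rose (7 and 2 adjusted over the list alone), among them the hyaluronan receptor CD44 (-2.59) and the transcription factor SOX9 (-2.21), with KLF4 higher (0.89; camera adjusted p = 0.0941; adjusted p = 0.219 with an estimated correlation). CCN2, a secreted target of TGF-beta, fell by 2.91 in the knockdown (camera adjusted p = 0.441 for its list) and by 2.04 with Dox in 22Rv1 (0.918). In LNCaP with Dox, 11 of 37 genes of the integrated stress response rose and 5 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.0597; adjusted p = 0.733 with an estimated correlation), with the stress factor DDIT3 at 1.66. With the within-group axis taken out 18 rose and 1 fell, the list's median went from 0.10 to 0.32 and camera's adjusted p was 6.73e-08. That p-value may be too small, since the fit counted no degrees of freedom for the axis. Markers of leukocytes and of stromal and endothelial cells had 7 tested genes each and were not called by camera in any comparison.

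The 226 genes that changed one way with Dox in both lines and the opposite way in the knockdown were 3.68 times the 61.4 expected from independent lists, but in 22Rv1 they moved while LGALS4 stayed flat (-0.06). In 1 of 100 drawn splits of the arrays within the lines, the real one, as many were found, and the highest other split gave 0. The 787 genes shared by both Dox comparisons also stood in 1 of 100 splits (highest other 0). No mixed split of the 22Rv1 arrays or of the LNCaP arrays called any gene, so these counts of 0 were all but fixed by the test. The splits therefore cannot tell whether either overlap exceeds chance. An axis of array or RNA quality that also varies within groups is a possible explanation: 95.1% of the 226 genes load on it in their Dox direction, and with it taken out 149 genes were found, 2.72 times the 54.7 then expected, and 87 of the first 226 were among them. Median scaling gave 46 (23 in each direction), and leaving out 1 array gave from 130 (without LNCaP Dox replicate 3) to 571 (without 22Rv1 Dox replicate 3). A response to galectin-4 stays open as untested, and how many of the 226 may follow the axis instead cannot be told apart from these values, since no measure of RNA quality is given in the sources used here.

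The splits were too few for a share under 0.05 in the remaining comparisons of 3 arrays with 3, each with 10 splits. As many genes as in the real split were found in 1 of the 10, the real one, for LNCaP Dox (3809, highest other 0), for the knockdown (3193, highest other 52) and for M4 against 22Rv1 (4849, highest other 0).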
